A study of Mus musculus with 6 samples.

How the data were processed

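T-cell receptor beta chain (TCRB) rearrangements were measured in 6 samples of T follicular regulatory (Tfr) cells sorted from the spleens of 3 Foxp3GFP mice. Tfr cells are Foxp3-expressing CD4 T cells of the B-cell follicle, and the GFP of this genotype reports Foxp3. Each mouse gave 1 sample titled superior and 1 titled inferior. The labels define these words no further, and they are used here as group names. Genomic DNA was extracted from the sorted cells and amplified with the immunoSEQ mouse TCRB kit at survey resolution, per the labels' protocols. A rearrangement in genomic DNA is present as 1 copy per allele and cell, so counts from DNA do not depend on expression.

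The deposited count per distinct nucleotide rearrangement is a whole number, and the sums differ between samples. The files do not say whether it counts templates (input DNA molecules) or reads. The sums, 667 to 1855 per sample, are of the size of a template count, and the counts are called templates here. The deposited productive frequency is a fraction, equal to the count divided by the sum of its sample. Build mm10 is named per the submitters' processing notes. The aligner, the clonotype caller and their filters are not given in the sources used here. The files hold rearrangements of 87 bases that end before the last CDR3 residue, without a stop codon in the CDR3 (complementarity-determining region 3), and all 6 samples carry 1 run label. In 41 rearrangements, with 0.682% of templates, the listed CDR3 did not start with cysteine, and these were left out of CDR3 features only. In 7 templates, 0.0994%, the J segment was not resolved, and these were left out of J usage only.

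A clonotype was a distinct nucleotide rearrangement. All 29 V and 14 J segment names matched symbols of the RefSeq gene table for GRCm38.p6, the assembly of mm10, which gave the coordinates on chromosome 6. Differences of single values between superior and inferior samples were tested with a two-sided exact permutation test over all 20 assignments of 3 against 3, whose smallest p is 0.1. Overlap and V usage distance within a mouse were set against those between mice over all 15 pairings of the samples, one-sided, with a smallest exact p of 0.0667. Neither test can reach 0.05. Mixing within a mouse was tested by 100000 random reassignments of its pooled templates to its 2 samples at their own totals. Single clonotypes of 5 or more templates in a mouse were compared between its 2 samples with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment within the mouse. Both within-mouse tests compare libraries and cover counting error only, as do the 95% Wilson intervals and the limits of 3 counts for a count of 0. Segment usage was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on templates summed per segment. It used total templates as library size, a common dispersion, segments of 10 or more templates and Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 was an alternative. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

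The tests, the segment lists, the rule for named segments and clonotypes and most alternatives were chosen before the data were examined. Named V segments were the 12 with the highest mean share and the 5 with the largest rise and the 5 with the largest fall among those tested. All tested J segments were named. Named clonotypes were the 3 largest of each sample, up to 5 per direction and mouse past the Fisher threshold, and up to 10 found in 2 or more mice. Ties were broken by nucleotide sequence among the largest of a sample, and otherwise by the clonotype's name. Clonotypes are named by V segment, CDR3 amino acids and J segment.

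On simulated counts with 2 changed segments, the edgeR step recovered 37.5% of 1.5-fold and 97.5% of 2-fold changes, for the 23 V and for the 12 J segments tested. The mixing step was tested on simulated data with evenly mixed templates, and 2 of 60 simulations passed the threshold. With evenly mixed cells that each gave 1 to 4 counted templates, the simulated ratio of observed to expected shared clonotypes was 0.309 to 0.345. It passed the threshold in all 3 mice, so the test does not separate uneven mixing from overstated counts. This simulation took the observed counts as cells, so it held more templates than the data. Its ratios lay above the 0.163 to 0.219 of the data. The Fisher step found 30 of 30 clones planted with 15 templates in the superior sample only, which had fewer templates than the inferior one in mice 1 and 3. Clones in the inferior sample only and smaller clones were not planted, and this step was not run on simulated overstated counts.

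The mouse number in the titles pairs the samples, since both come from the same animal. Deviations from the group means over V segments correlated at 0.079, -0.253 and -0.291 between the samples of mice 1, 2 and 3, and over J segments at 0.146, 0.716 and 0.211. Alternatives were the mouse as a block, each mouse left out, thinning to 667 templates, clonotypes by CDR3 amino acids, other indices, count minimums and scalings. Merging rearrangements with the same V segment, CDR3 nucleotides and J segment, counting each such combination once, and counting up to 2, 3, 4 or 5 templates of a merged clonotype as 1 cell were added after seeing the data. Alternatives that need read counts, non-productive rearrangements or N nucleotides were not run, and the productive share and N nucleotides were not analysed here.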

Results

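The data were productive TCRB rearrangements from the genomic DNA of splenic Tfr cells of 3 mice, with 1 superior and 1 inferior sample per mouse. The 6 samples held 7043 templates and 4238 distinct rearrangements, or 3807 after merging those with the same V segment, CDR3 nucleotides and J segment. The superior samples of mice 1, 2 and 3 held 667, 1095 and 1136 templates in 455, 685 and 760 rearrangements. The inferior samples held 1370, 920 and 1855 templates in 835, 562 and 1112 rearrangements. Templates averaged 966 ± 260 (SD, n = 3) in superior and 1382 ± 468 (n = 3) in inferior samples, a difference that did not pass the exact permutation test (p = 0.3). Distinct rearrangements averaged 633 ± 159 and 836 ± 275 (n = 3 each, exact p = 0.4), and after thinning to 667 templates 483 ± 29.6 and 495 ± 41.1 (exact p = 0.8). Both were higher in the superior sample of mouse 2 only, and without mouse 2 the difference in templates, superior minus inferior, moved from -416 to -711 and that in rearrangements from -203 to -366. Without mouse 1 they were -272 and -114.5, and without mouse 3 -264 and -128.5.

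The labels state no purpose for the superior and inferior samples. Their design allows the repertoire of both samples of a mouse to be compared, and overlap within a mouse to be set against overlap between mice.

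Tfr repertoires were diverse in both groups, with no rearrangement above 35 templates, 3.8% of its sample. Single-template rearrangements made up 60.6% to 71.2% of the rearrangements of a sample. Shannon clonality, which is 0 when all clones have equal size, was 0.0258 ± 0.00535 in superior and 0.0311 ± 0.00588 in inferior samples (SD, n = 3 each), and was lower in the superior sample in 3 of 3 mice (exact permutation p = 0.2). After thinning to 667 templates it was 0.0212 ± 0.00509 and 0.0219 ± 0.00918 (exact p = 1), and higher in the superior sample in 2 of 3 mice. The 10 largest clonotypes held 7.28% ± 1.97 and 7.36% ± 2.99 of templates (n = 3 each, exact p = 1), and the difference turned to 0.707 points without mouse 2. Clonotypes of 2 or more templates held 54.6% ± 3.34 in superior and 61.7% ± 1.86 in inferior samples (n = 3 each, exact p = 0.1, the smallest possible). Thinning to equal depth turned the last difference to 45.5% in superior against 42.9% in inferior samples.

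The largest clonotype of all samples was TRBV2 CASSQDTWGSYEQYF TRBJ2-7, with 35 templates in the inferior sample of mouse 2, a share of 3.8% (95% interval 2.75 to 5.24), and 10 templates, 0.913%, in the superior sample. With its repeats merged it had 36 and 11 templates. The next in that inferior sample were TRBV2 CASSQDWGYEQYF TRBJ2-7 with 8 templates and TRBV16 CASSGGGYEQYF TRBJ2-7 with 7. The superior sample of mouse 2 was led by TRBV13-3 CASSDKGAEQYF TRBJ2-7 with 13 templates, 1.19% (0.695 to 2.02), and by TRBV2 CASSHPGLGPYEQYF TRBJ2-7 and TRBV15 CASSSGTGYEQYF TRBJ2-7 with 11 templates each. All 3 also had 3 templates in the inferior sample. In mouse 1, the superior sample was led by TRBV29 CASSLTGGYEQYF TRBJ2-7, TRBV26 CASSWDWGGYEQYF TRBJ2-7 and TRBV13-3 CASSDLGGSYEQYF TRBJ2-7, with 8, 7 and 6 templates. The inferior sample was led by TRBV16 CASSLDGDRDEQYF TRBJ2-7 and TRBV15 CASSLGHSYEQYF TRBJ2-7 with 13 templates each and TRBV4 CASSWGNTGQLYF TRBJ2-2 with 12. In mouse 3, TRBV15 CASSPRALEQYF TRBJ2-7 had 7 templates in the superior sample, 0.616% (0.299 to 1.27), and TRBV3 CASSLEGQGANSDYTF TRBJ1-2 and TRBV31 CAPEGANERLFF TRBJ1-4 had 6. The inferior sample was led by TRBV2 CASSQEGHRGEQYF TRBJ2-7 with 11 templates, 0.593% (0.331 to 1.06), TRBV13-1 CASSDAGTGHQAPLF TRBJ1-5 with 10 and TRBV2 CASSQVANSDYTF TRBJ1-2 with 9.

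Clonotypes were shared mainly within a mouse. The superior and inferior samples of mice 1, 2 and 3 shared 38, 58 and 66 rearrangements, against 0 to 4 for samples of different mice. The Morisita-Horn index, which weighs shared clones by size, was 0.133, 0.234 and 0.0737 within mice, a mean of 0.147 ± 0.0813 (SD, 3 pairs), and 0.00113 ± 0.0019 over the 12 pairs between mice. Shared clonotypes held 11.3% ± 4.05 of templates within mice and 0.133% ± 0.216 between mice. The true pairing gave the largest difference of the 15 pairings (one-sided exact permutation p = 0.0667, the smallest possible). V segment usage was no closer within a mouse than between mice, with a Jensen-Shannon distance of 0.136 ± 0.0244 and 0.136 ± 0.0249 (exact permutation p = 0.533).

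**Figure D1:**
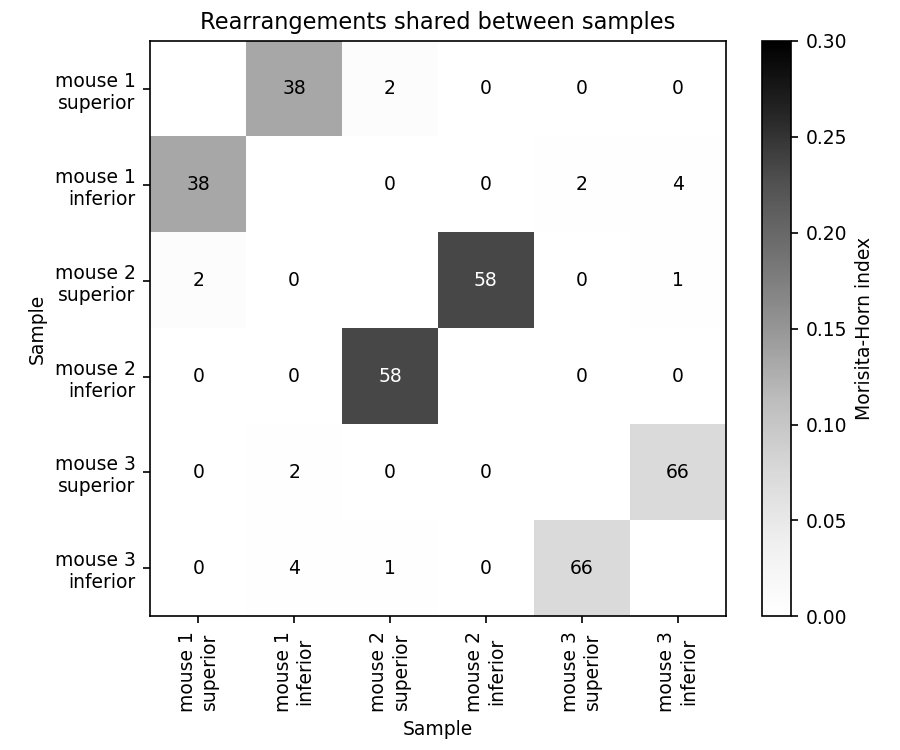
Rearrangements found in both samples of each pair of the 6 samples (numbers in the cells) and their Morisita-Horn index (grey scale, no unit). The 3 same-mouse pairs share 38, 58 and 66 rearrangements, and pairs of different mice share 0 to 4.

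The superior and inferior samples of a mouse shared fewer clonotypes than even mixing of their templates gives. Mouse 1 had 38 shared rearrangements where even mixing gave 232 (95% range 214 to 249), a ratio of 0.164. Mouse 2 had 58 against 265 (246 to 283), a ratio of 0.219, and mouse 3 had 66 against 405 (382 to 428), a ratio of 0.163. The two-sided permutation p was 2e-05 in each mouse, the smallest that 100000 reassignments give. The Morisita-Horn index was also below even mixing, with 0.133, 0.234 and 0.0737 observed and 0.450, 0.579 and 0.408 under even mixing (permutation p = 2e-05 in each mouse). Even mixing assumes that each counted template is a separate cell, which the data do not show. Simulated evenly mixed cells with 1 to 4 templates each also passed this test, at ratios of 0.309 to 0.345 and with more templates than the data. With rearrangements of the same V segment, CDR3 nucleotides and J segment merged and up to 2, 3, 4 or 5 templates counted as 1 cell, chosen after seeing the data, the mean ratio over the mice was 0.372, 0.739, 1.07 and 1.39, a rise that this counting gives by construction. By shared clonotypes, mouse 2 did not pass the threshold at 3 templates per cell, and no mouse passed at 4. At 5, mice 2 and 3 passed in the other direction. By the Morisita-Horn index, mouse 2 did pass at 3 templates per cell (0.186 observed, 0.224 under even mixing, permutation p = 0.0294).

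Over the 3 mice together, larger clones were found in both samples more often. After merging rearrangements with the same V segment, CDR3 nucleotides and J segment, 6.57% (95% interval 5.64 to 7.65) of single-template clonotypes of one sample were found in the other sample of the mouse. The share was 8.09% (6.80 to 9.58) for clonotypes of 2 to 4 templates, 21.9% (16 to 29.3) for 5 to 9 templates and 60.0% (35.7 to 80.2) for 10 or more, the last over 15 clonotypes only. For 10 or more templates it was 3 of 7 clonotypes in mouse 1, 6 of 6 in mouse 2 and 0 of 2 in mouse 3, and 33.3% (12.1 to 64.6) without mouse 2. For 5 to 9 templates it was 24.4%, 32.6% and 12.9% in mice 1, 2 and 3, and in mouse 3 the interval (6.69 to 23.4) overlapped that of single-template clonotypes (5.62 to 8.85). Even mixing gave 36.6%, 51.4%, 85.1% and 98.3%. A clonotype in both samples enters these shares once from each sample, and the intervals take the entries as independent, so they may be too narrow. Among shared rearrangements, sizes in both samples correlated in mouse 1 (Spearman's rho 0.617, Pearson's r of log2 sizes 0.613, permutation p of rho 5e-05, adjusted 0.00015) and mouse 2 (rho 0.368, r 0.396, p = 0.0047, adjusted 0.00705). In mouse 3 the correlation did not pass the threshold (rho 0.220, r 0.214, permutation p = 0.0769, adjusted 0.0769). These correlations are across clonotypes, which are not independent replicates, and cover 3 relations.

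**Figure D2:**
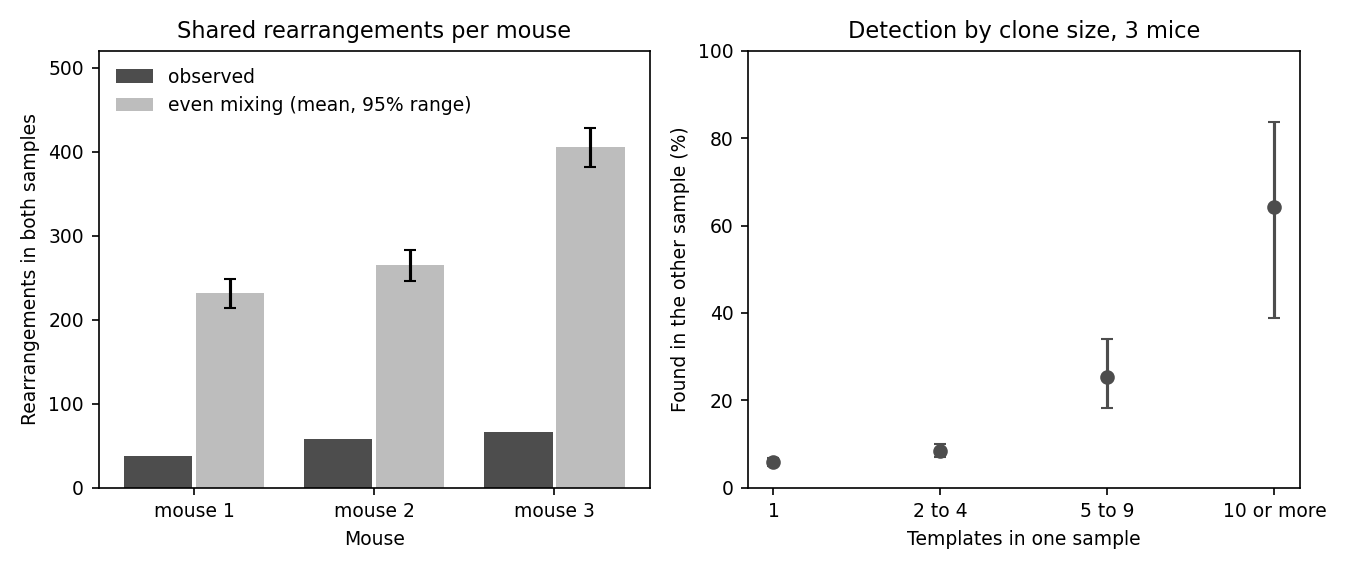
Left, rearrangements found in both samples of each mouse (count), observed and as the mean and 95% range under even mixing. Right, the share (%) of rearrangements of one sample found in the other sample of the mouse, by templates in the first sample, with 95% Wilson intervals over 3 mice. The share is 5.83% for 1 template and 64.3% for 10 or more. Rearrangements in both samples enter once from each, and the intervals take these entries as independent.

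In template counts, some clonotypes differed between the superior and inferior library of each mouse. Fisher's exact test called 7 of 43 clonotypes in mouse 1, 9 of 43 in mouse 2 and 15 of 57 in mouse 3. In mouse 1, 6 were higher in the superior sample. TRBV29 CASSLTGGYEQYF TRBJ2-7 had 8 of 667 templates, 1.20%, and 0 of 1370 in the inferior sample, which allows up to 0.219% (adjusted Fisher's exact p = 0.00552). TRBV26 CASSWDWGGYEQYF TRBJ2-7 with 7 templates (adjusted p = 0.00849), TRBV13-3 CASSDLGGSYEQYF TRBJ2-7 with 6 (adjusted p = 0.0174), and TRBV19 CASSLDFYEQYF TRBJ2-7 and TRBV2 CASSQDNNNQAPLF TRBJ1-5 with 5 each (adjusted p = 0.0267) were also listed in the superior sample only. TRBV15 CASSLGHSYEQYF TRBJ2-7 was higher in the inferior sample, with 13 templates against 0 of 667, which allows up to 0.450% (adjusted p = 0.0431).

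In mouse 2, 6 of the called clonotypes were higher in the inferior sample, and all 5 named ones used TRBV2. Over all samples TRBV2 held 780 templates in 309 listed rearrangements, against 849 in 584 for TRBV13-2, so its rearrangements had more templates on average. TRBV2 was also the most frequent V segment among all clonotypes tested in mouse 2. Several of these were listed in the superior sample only, such as TRBV2 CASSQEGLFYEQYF TRBJ2-7 with 6 templates (adjusted Fisher's exact p = 0.0874). Whether TRBV2 was more frequent among the called clonotypes than among all that reached the minimum was not tested. TRBV2 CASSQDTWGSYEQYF TRBJ2-7 stood at 3.8% against 0.913% (adjusted Fisher's exact p = 0.000535), and TRBV2 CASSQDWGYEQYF TRBJ2-7 had 8 templates against 0 of 1095, which allows up to 0.274% (adjusted p = 0.0399). TRBV2 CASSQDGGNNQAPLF TRBJ1-5, TRBV2 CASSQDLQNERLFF TRBJ1-4 and TRBV2 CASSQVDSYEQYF TRBJ2-7 had 6 templates each in the inferior sample only. TRBV13-3 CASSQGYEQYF TRBJ2-7 had 9 templates, and TRBV26 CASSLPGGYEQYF TRBJ2-7 and TRBV31 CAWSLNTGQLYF TRBJ2-2 had 8, in the superior sample and 0 of 920 in the inferior one, which allows up to 0.326% (adjusted p = 0.0448 for these 6). In mouse 3, 14 of the 15 were higher in the superior sample, among them TRBV15 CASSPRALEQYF TRBJ2-7 with 7 templates and TRBV13-1 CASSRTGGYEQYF TRBJ2-7, TRBV3 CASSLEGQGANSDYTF TRBJ1-2 and TRBV3 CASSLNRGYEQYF TRBJ2-7 with 6. TRBV12-1 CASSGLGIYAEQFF TRBJ2-1 had 5, and these 5 clonotypes had 0 of 1855 templates in the inferior sample, which allows up to 0.162% (adjusted p = 0.0320 each). TRBV2 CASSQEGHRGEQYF TRBJ2-7 was higher in the inferior sample, with 11 templates against 0 of 1136, which allows up to 0.264% (adjusted p = 0.0343).

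Fisher's test takes each template as a separate cell, and most called clonotypes had 5 to 9 templates against 0, which is few cells if 1 cell gave several templates. The count per direction depends on depth, since a clone of 5 templates passes only when it is absent from the deeper sample. With a minimum of 10 templates the calls were 0 of 9 in mouse 1 (3 at unadjusted Fisher's exact p under 0.05), 1 of 6 in mouse 2 and 2 of 4 in mouse 3, where the direction turned to 0 higher in the superior and 2 in the inferior sample, and with a minimum of 3 templates 2 of 158, 1 of 153 and 0 of 262 (32 at unadjusted p under 0.05 in mouse 3).

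Few clonotypes were shared between mice. By nucleotides, 9 of 4238 rearrangements were found in 2 or more mice, with 0.554% of templates, and 0 in all 3 mice. By V segment, CDR3 amino acids and J segment, 30 of 3751 were found in 2 or more mice, with 2.51% of templates, and 23 of the 30 had more than 1 CDR3 nucleotide form. The clonotype found in all 3 mice was TRBV13-2 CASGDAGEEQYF TRBJ2-7, with 2 templates in the inferior sample of mouse 1, 3 in the inferior sample of mouse 2 and 2 in the superior sample of mouse 3. Those found in 2 mice with the most templates were TRBV2 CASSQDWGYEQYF TRBJ2-7 with 17 templates, TRBV15 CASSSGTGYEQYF TRBJ2-7 with 16, TRBV13-2 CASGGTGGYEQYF TRBJ2-7 with 15, and TRBV13-2 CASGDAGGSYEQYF TRBJ2-7, TRBV2 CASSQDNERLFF TRBJ1-4 and TRBV3 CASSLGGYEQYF TRBJ2-7 with 9 each. TRBV26 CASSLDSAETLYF TRBJ2-3 had 8, and TRBV2 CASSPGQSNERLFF TRBJ1-4 and TRBV3 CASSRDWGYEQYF TRBJ2-7 had 7 each. Without mouse 1 the number by nucleotides was 1, and without mouse 3 it was 2.

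TRBV13-2, TRBV2, TRBV3 and TRBV19 were the most used V segments in both groups, and no V segment passed the test between superior and inferior samples. TRBV13-2 (chromosome 6, 41121396 to 41121832, mm10) held 10.2% ± 2.62 in superior and 13.6% ± 2.65 in inferior samples (SD, n = 3 each), log2 superior over inferior -0.38 (SE 0.23, edgeR adjusted p = 0.852). TRBV2 (41047556 to 41047995) held 10.2% ± 1.8 and 11.7% ± 1.65, lower in the superior sample in 3 of 3 mice. TRBV3 (41048394 to 41048824) held 11% ± 1.62 and 9.58% ± 0.715, and TRBV19 (41178589 to 41179048) 10.6% ± 0.689 and 9.30% ± 0.176, both higher in the superior sample in 3 of 3 mice. TRBV5 held 7.09% and 7.25%, TRBV16 5.53% and 4.96%, TRBV20 4.66% and 5.06%, TRBV13-3 4.94% and 4.73%, and TRBV1 5.0% and 4.65%. TRBV31 held 4.64% and 3.99%, TRBV15 3.91% and 4.35%, and TRBV26 3.93% and 4.24%.

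edgeR's quasi-likelihood test called 0 of 23 V segments, with 1 at unadjusted p under 0.05, and DESeq2 called 0, with 0 at unadjusted p under 0.05. That 1 segment was TRBV14, with 1.24% ± 0.485 in superior and 0.562% ± 0.160 in inferior samples (n = 3 each), higher in the superior sample in 3 of 3 mice. Its log2 difference was 1.13 (SE 0.43, edgeR unadjusted p = 0.0198, adjusted p = 0.456). It was 0.73 with each rearrangement counted once and 0.66 with each combination of V segment, CDR3 nucleotides and J segment counted once, the latter chosen after seeing the data, and edgeR had 0 V segments at unadjusted p under 0.05 in both. The other largest positive log2 differences were 0.50 for TRBV29, which the RefSeq table lists as a pseudogene (0.03 without mouse 1, 1.0 without mouse 3), 0.28 for TRBV17, 0.20 for TRBV3 and 0.19 for TRBV19. The largest negative ones were -0.99 for TRBV21, -0.44 for TRBV23, -0.38 for TRBV13-2, -0.18 for TRBV12-2 and -0.17 for TRBV2, all with edgeR adjusted p = 0.852. TRBV21 rested on 16 templates over all samples (SE 0.97). It had 0% in the superior sample of mouse 1 and the inferior sample of mouse 2, and its highest share, 0.539%, in the inferior sample of mouse 3. TRBV21 was -2.53 without mouse 2, and TRBV13-2 was -0.12 without mouse 1, -0.61 without mouse 3 and -0.13 with each combination of V segment, CDR3 nucleotides and J segment counted once. The differences of TRBV13-3, TRBV17, TRBV2 and TRBV31 turned in sign under at least 1 other weighting or tool. Leaving out mouse 1 turned TRBV15, TRBV16, TRBV17 and TRBV5, leaving out mouse 2 turned TRBV12-2, TRBV13-3, TRBV31 and TRBV5, and leaving out mouse 3 turned TRBV23.

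**Figure D3:**
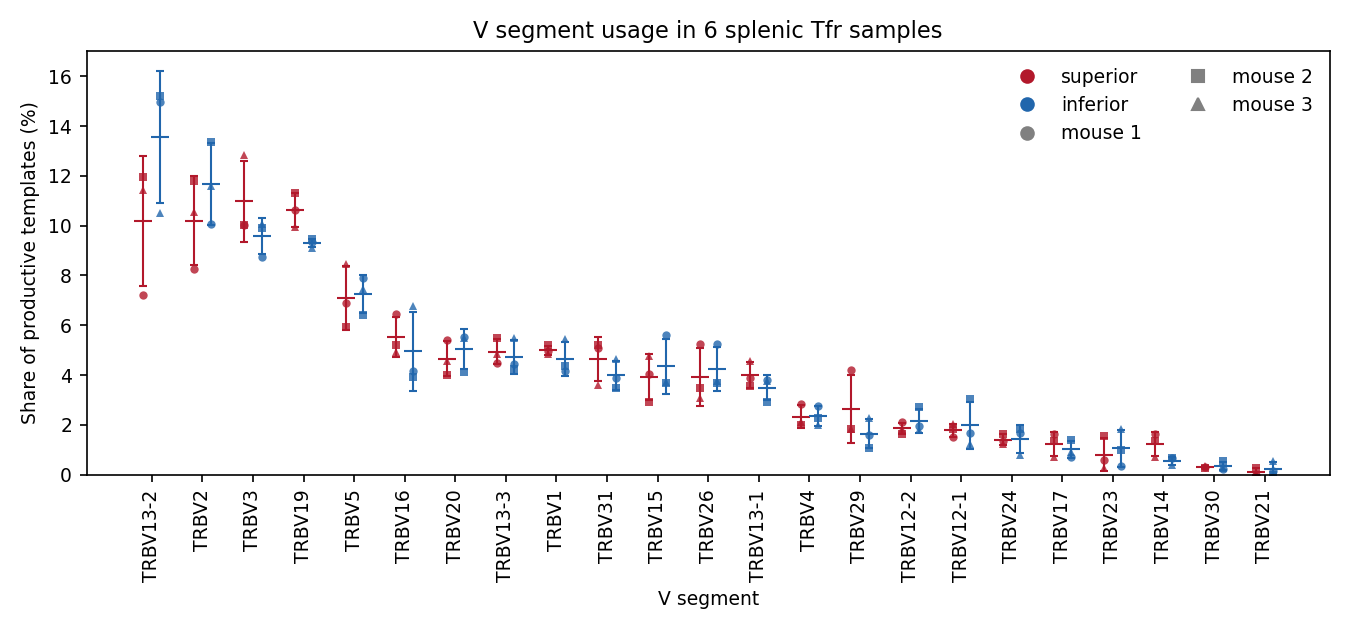
Share (%) of productive templates per tested V segment in the 6 samples, by group (colour) and mouse (symbol), with the group mean (bar) and SD (error bar, n = 3). TRBV13-2 spans 7.20% to 15.2%, and 0 of 23 segments passed the edgeR threshold.

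By templates, J segment usage was dominated by TRBJ2-7 (chromosome 6, 41543810 to 41543856, mm10), with 33.8% ± 4.09 in superior and 31.4% ± 4.22 in inferior samples (SD, n = 3 each). By V segment, CDR3 amino acids and J segment, 19.6% of the 3721 clonotypes found in 1 mouse used TRBJ2-7, so its clonotypes had more templates on average. Most of the 3 largest clonotypes of each sample and most of those called by Fisher's test used it too. Whether the count per clonotype depends on the J segment was not tested. TRBJ2-5 held 9.45% and 8.79%, TRBJ2-1 9.11% and 8.91%, TRBJ2-4 6.59% and 6.63%, TRBJ2-3 5.70% and 5.46%, and TRBJ2-2 5.46% and 6.08%. In the TRBJ1 cluster, TRBJ1-4 held 6.87% and 7.48%, TRBJ1-3 6.58% and 7.69%, TRBJ1-1 5.71% and 4.96%, TRBJ1-2 5.25% and 5.41%, and TRBJ1-6 1.57% and 2.10%. TRBJ2-7, TRBJ2-5 and TRBJ1-1 were higher in the superior sample in 3 of 3 mice, and TRBJ1-3 and TRBJ1-6 were lower in 3 of 3. For the other segments listed so far the direction differed between mice. edgeR called 0 of 12 J segments, with 1 at unadjusted p under 0.05, and DESeq2 called 0, with 0 at unadjusted p under 0.05. That 1 segment was TRBJ1-5, with 3.62% ± 1.06 and 5.08% ± 0.712 (n = 3 each), lower in the superior sample in 3 of 3 mice. Its log2 difference was -0.49 (SE 0.22, edgeR unadjusted p = 0.0491, adjusted p = 0.590). Without mouse 3, edgeR called TRBJ1-5 (adjusted p = 0.0403), and the differences of TRBJ1-2, TRBJ1-4, TRBJ2-1, TRBJ2-4 and TRBJ2-5 turned in sign under at least 1 other weighting, scaling or tool. Leaving out mouse 3 turned TRBJ1-2, TRBJ2-1, TRBJ2-3 and TRBJ2-4, and leaving out mouse 2 turned TRBJ2-1.

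The lists of segments showed no difference that passed its test, which cannot go below an exact p of 0.1. V segments associated with invariant natural killer T cells (TRBV13-1, TRBV13-2, TRBV13-3, TRBV29 and TRBV1) held 26.8% ± 1.78 of templates in superior and 28.1% ± 0.779 in inferior samples (SD, n = 3 each, exact permutation p = 0.5, adjusted over the 7 lists 0.817). Those associated with mucosal-associated invariant T cells (TRBV19 and the TRBV13 segments) held 29.8% ± 3.17 and 31.1% ± 1.94 (exact p = 0.6, adjusted 0.817). Both lists were higher in the superior sample in 2 of 3 mice, and without mouse 1 their differences turned to 0.135 and 1.20 percentage points. Segments reactive with endogenous mammary tumour virus superantigens (TRBV12-1, TRBV12-2, TRBV15, TRBV16, TRBV24 and TRBV26) held 18.4% ± 2.05 and 19.1% ± 1.14 (exact p = 0.7, adjusted 0.817), and the difference turned to 0.0406 points without mouse 2. TRBV1 and TRBV31, at the ends of the locus, held 9.64% ± 1.04 and 8.65% ± 1.25 (exact p = 0.3, adjusted 0.7), a difference of 0.193 points without mouse 2 and 2.30 without mouse 3. The TRBJ1 cluster held 29.7% ± 1.70 and 32.7% ± 3.42, lower in the superior sample in 3 of 3 mice, and the TRBJ2 cluster 70.3% and 67.3% (exact p = 0.3, adjusted 0.7). V segments outside the 22 usually functional ones held 0.668% ± 0.461 and 0.579% ± 0.122 (exact p = 0.9, adjusted 0.9), and the difference turned to -0.247 points without mouse 1. The V segments of these lists are also used by conventional T cells, so their shares do not count those cell types.

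No difference in CDR3 features passed its test, which cannot go below an exact p of 0.1. The CDR3 averaged 13.68 ± 0.0188 amino acids in superior and 13.75 ± 0.105 in inferior samples (SD, n = 3 each, exact permutation p = 0.4, adjusted 0.8), a difference of -0.0758 that was -0.139 without mouse 1 and -0.0154 without mouse 2. Kyte-Doolittle hydropathy at CDR3 positions 6 and 7, counted from 1 at the conserved cysteine, averaged -1.10 ± 0.143 and -1.13 ± 0.0665 (exact p = 0.9, adjusted 0.9), and the difference turned to -0.0186 without mouse 1.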

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

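The D segment column was used in no comparison, and in it some templates with a TRBJ1 segment were given TRBD2. Of 2244 templates with a TRBJ1 segment, 122, or 5.44% (95% interval 4.57 to 6.45), were given TRBD2. TRBD2 lies downstream of the TRBJ1 cluster, so joining by deletion of the DNA between them is not possible for this pair. The share ranged from 3.37% in the superior sample of mouse 3 to 10.1% in the superior sample of mouse 2. The D segment was not resolved in 19% of all templates. No explanation was tested.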

How the results depend on the processing

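Merging rearrangements by V segment, CDR3 nucleotides and J segment, counting each such combination once, and counting several templates as 1 cell were chosen after seeing the data. Overlap stayed higher within than between mice under each alternative, with differences of the Morisita-Horn index from 0.102 to 0.182 when a mouse was left out and 0.121 after thinning. The ratio of observed to evenly mixed shared clonotypes lay between 0.113 and 0.219 in every mouse by nucleotides, by amino acids, after merging, among clonotypes of 2 or more templates and without the largest clonotypes. The minimum of 2 templates drops shared clonotypes with 1 template in each sample, 13, 20 and 23 in mice 1, 2 and 3. This lowers the ratio by construction. The ratio rose when several templates of merged clonotypes were counted as 1 cell. In mice 1, 2 and 3 it was 0.335, 0.422 and 0.359 with up to 2 templates per cell. With up to 3 it was 0.698, 0.848 and 0.672. Mouse 2 then no longer passed the threshold by shared clonotypes, but passed by the Morisita-Horn index (permutation p = 0.0294). The ratio was 0.985, 1.16 and 1.07 with up to 4, where no mouse passed. It was 1.26, 1.45 and 1.45 with up to 5, where mice 2 and 3 passed in the other direction. Counting more templates as 1 cell lowers the expected number at the same observed one, so the ratio rises by construction. edgeR with the mouse as a block called 0 V segments (1 at unadjusted p under 0.05) and 0 J segments (1 at unadjusted p under 0.05), and the block changed no other call, with TRBV14 at 1.10 and TRBJ1-5 at -0.43. Read weights, non-productive rearrangements and N nucleotides were not run. In simulations at the depths used, with 3 samples per group, the segment test recovered 37.5% of 1.5-fold changes in segments of middle share. Other depths, and changes in rarer or more used segments, were not simulated. Depth limits single clonotypes, since a count of 0 allows up to 0.162% to 0.450% of templates. The exact tests of 3 against 3 cannot pass 0.05 at any depth, so their side of the threshold says nothing about stability. The following differences, superior minus inferior, turned in sign or moved, and the cause was not tested. With a mouse left out, templates ranged from -711 to -264, distinct rearrangements from -366 to -114.5 and CDR3 length from -0.139 to -0.0154 amino acids. Clonality by the Simpson index was 0.00147. The share of the 10 largest clonotypes was 0.00141 points after merging and 1.11 among clonotypes of 2 or more templates, and -0.489 to 0.707 with a mouse left out. The share in clonotypes of 2 or more templates was 2.53 points after thinning. With a mouse left out, the invariant natural killer T list ranged from -2.09 to 0.135 points, the mucosal-associated list from -2.92 to 1.20, the superantigen list from -1.22 to 0.0406, the ends of the locus from 0.193 to 2.30, the TRBJ1 cluster from -4.29 to -1.89, segments outside the 22 from -0.247 to 0.277 and hydropathy from -0.0186 to 0.0544. With each rearrangement counted once, the invariant natural killer T list was -2.15 points and the mucosal-associated list -2.23. The superantigen list was then -0.387, the TRBJ1 cluster -1.42 and segments outside the 22 0.0355. V usage distance, same mouse minus different mice, ranged from -0.00523 to 0.0061 and was 0.00393 with each rearrangement counted once. Fisher calls in mice 1, 2 and 3 were 0, 1 and 2 at 10 or more templates and 2, 1 and 0 at 3 or more, where fewer or more clonotypes were tested. Clonotypes in 2 or more mice ranged from 1 to 6 with a mouse left out, were 4.61 on average after thinning and 30 by amino acids. J segments called ranged from 0 to 1, the 1 being TRBJ1-5 without mouse 3. For log2 differences, none past the threshold, each rearrangement counted once gave -0.21 for TRBV13-3, -0.029 for TRBV17, 0.10 for TRBV2, 0.038 for TRBJ1-2, 0.031 for TRBJ1-4, -0.020 for TRBJ2-1 and -0.024 for TRBJ2-5. Each merged combination counted once gave -0.13 for TRBV13-2, 0.098 for TRBV3, 0.040 for TRBV19, 0.27 for TRBV29, -0.15 for TRBV13-3, -0.0078 for TRBV17, 0.086 for TRBV2, -0.00054 for TRBV31, 0.012 for TRBJ1-2, 0.16 for TRBJ1-4 and -0.034 for TRBJ2-5. DESeq2 gave -0.027 for TRBV13-3, 0.015 for TRBJ1-2 and 0.029 for TRBJ2-4, TMM factors gave 0.030 for TRBJ1-2 and 0.046 for TRBJ2-4, and leaving out the largest clonotype of each sample gave -0.048 for TRBV13-3. TRBV14 was 0.73 with each rearrangement and 0.66 with each merged combination counted once. With a mouse left out, TRBV21 ranged from -2.53 to -0.93 (not tested without mouse 3, with too few templates), TRBV13-2 from -0.61 to -0.12, TRBV29 from 0.026 to 1.0, TRBV12-2 from -0.32 to 0.064, TRBV13-3 from -0.092 to 0.22, TRBV15 from -0.49 to 0.052, TRBV16 from -0.13 to 0.50, TRBV17 from -0.093 to 0.54, TRBV23 from -1.55 to 0.92, TRBV31 from -0.0037 to 0.48, TRBV5 from -0.18 to 0.044, TRBJ1-2 from -0.33 to 0.28, TRBJ2-1 from -0.10 to 0.18, TRBJ2-3 from -0.18 to 0.22 and TRBJ2-4 from -0.16 to 0.16.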

Other observations

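The tests in this part were chosen after the results were seen, except the splits of the samples.

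Clonotypes found in several mice mostly had different nucleotides in each. Of 32 pairs of rearrangements from different mice with the same V segment, CDR3 amino acids and J segment, 9 had the same CDR3 nucleotides, 28.1% (95% interval 15.6 to 45.4). TRBV13-2 was used by 8 of the 30 clonotypes found in 2 or more mice and TRBJ2-7 by 9. TRBJ2-7 was used by 731 of the 3721 clonotypes found in 1 mouse. TRBV13-2 was used by 584 of the 4409 listed rearrangements, a count that includes repeats of the same CDR3. Neither difference was tested. V segments outside the 22 usually functional ones held 30 rearrangements with 41 templates, over 7 segments. Of these 30, 13 had a listed CDR3 without a leading cysteine, among them all 7 that used TRBV27.

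TRBV13-2, the V segment with the highest mean share over all samples, was lower in the superior sample in mice 1 and 2. Its share was 7.20% in the superior and 15% in the inferior sample of mouse 1 (Fisher's exact p = 3.05e-07, adjusted over 3 mice 9.14e-07). It was 12% and 15.2% in mouse 2 (exact p = 0.0359, adjusted 0.0539), and 11.4% and 10.5% in mouse 3 (exact p = 0.432, adjusted 0.432). These tests compare libraries, take each template as a separate cell and cover counting error only. Over the 3 mice the log2 difference was -0.38 by templates and -0.13 with each combination of V segment, CDR3 nucleotides and J segment counted once. A hypothesis that the difference was confined to mouse 1 was set up and later dropped, after its test had not decided it, since mouse 2 differed by -3.25 percentage points.

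Fewer clonotypes lay in both samples of a mouse than even mixing gives, with ratios of 0.164, 0.219 and 0.163. Clones split by sequence differences upstream of the CDR3 are argued against, because merging by V segment, CDR3 nucleotides and J segment left the highest ratio of the 3 mice at 0.183. Counts per rearrangement that overstate the number of cells stay open: merged clonotypes of 2 to 4 templates were found in the other sample 1.23 times (95% interval 0.978 to 1.55) as often as single ones, which holds both 1 and the 1.40 of even mixing, while by nucleotide rearrangement the value was 1.44 (1.15 to 1.81), which holds the 1.48 of even mixing and not 1. A clonotype in both samples enters once from each, among them 13, 20 and 23 rearrangements with 1 template in both samples of mice 1, 2 and 3. Both intervals take such entries as independent and may be too narrow, so the exclusion of 1 is uncertain. Taken alone, the value by nucleotide rearrangement would go against each such clonotype being 1 cell, not against counts that overstate cells in part. By nucleotide rearrangement there were 2880 single-template entries, against 2328 after merging. Entries that merging joins can raise the value, so it does not decide this question. The rule for reading this test was changed more than once after results were seen: it first took 1.40 inside the interval as evidence against the explanation, and later needed both definitions to give the same outcome. Clones expanded among the cells of only 1 of the 2 samples may also account for it. Merged clonotypes of 10 or more templates in the 2 samples together numbered 10, 8 and 4 in mice 1, 2 and 3. Of these, 4, 0 and 2, or 6 in all, lay in 1 sample only, where even mixing gives 0.0924, 0.00647 and 0.0182. Overstated counts give such clonotypes too, and the 2 explanations cannot be told apart.

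Within a sample, 466 of 4409 listed rearrangements repeated the V segment, CDR3 amino acids and J segment of another. Separate recombinations are argued against as the main source, since 6.44% of the repeats differed in their CDR3 nucleotides. The other 93.6% (95% interval 91.0 to 95.5) had identical CDR3 nucleotides and differed upstream, which is consistent with sequence differences in copies of 1 rearrangement. Of these 436, 99 differed from the largest of their set by up to 3 substitutions, 307 by 1 inserted or deleted base, and 30 by more. Such repeats made up 26% of the rearrangements with TRBV24, 25.9% with TRBV13-2, 21.5% with TRBV29 and 17.5% with TRBV16.

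In the count of V segments called by edgeR between superior and inferior samples, the real split of the samples gave 0 and the highest of the other splits 1. For J segments the real split gave 0 and the highest other 0. A count of 0 is reached by any split, so all 10 of the 10 splits have as many calls, and 10 splits are too few for a share under 0.05.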
